A study of Mus musculus with 21 samples.

How the data were processed

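RNA was measured by sequencing in 21 libraries of E14 mouse embryonic stem cells in 7 groups of 3: cells in standard culture (ES), and cells at days 3, 5 and 7 of differentiation with vehicle or with 20 µM pyridoxine (VB6). The labels give total RNA extracted with TRIzol, while their protocol text also speaks of small RNA enrichment, so how the libraries were prepared is uncertain. Groups were taken from the labels, and every library matched a column of the deposited tables.

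The authors deposited 3 tables with 78317 gene rows each, 21909 of them without a symbol. The deposited expected counts are estimated counts per gene, not normalized, of which 26.9 to 30.5% of values above 0 per library were not whole. The authors also deposited TPM (each library summing to the same total) and FPKM. Within a library the ratio of TPM to FPKM was constant over genes to within 0.11% (the range holding the middle 90% of genes). The reads were placed on mm10, per the submitters' processing notes, and the aligner, the counting program and the annotation release are not given in the sources used here. Gene positions, GC content and transcript lengths came from GENCODE M21, which uses mm10. Of the gene IDs, 26830 are not in that annotation, and they held 1.92% of the counts.

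Total expected counts ran from 15882380 to 21629730 per library. Expected counts were rounded to whole numbers first, which changed the sum over libraries by 0.0002%. The design had been written for whole counts, and the same test was kept. Genes passing edgeR's filterByExpr with the 7 groups were tested, 18901 in all, after TMM normalization. The edgeR quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3, limma 3.58.1) was fitted over all 21 libraries with a mean per group, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Comparisons were VB6 against vehicle at each day, the mean of those 3 differences, whether they differ between days, and vehicle day 3 against ES, day 5 against day 3 and day 7 against day 5. SE values were derived from the log2 fold change and the F statistic.

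The 37 gene lists were fixed before the data were examined, as were the tests, the comparisons and the first set of alternatives. Each was tested with camera (limma, preset correlation 0.01, log2 CPM with a prior count of 2) where at least 5 members were tested, with adjustment over lists within a comparison. Members called are counted with adjustment over all genes, and the count adjusted over the list alone is given where it differs. Some genes belong to more than 1 list. Position on the vehicle axis was the projection of a library on the log2 difference from ES of a vehicle group of another day. That group was chosen so that no library of a comparison sets its axis, and exact two-sided permutation tests were used. Annotation terms carried by the deposited tables with 10 to 300 tested genes were tested by one-sided Fisher exact tests among 17147 tested genes with a term.

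Named genes followed a rule: the 8 highest and 8 lowest log2 fold changes per comparison (called, protein-coding, not a predicted gene, mean CPM of at least 1 in the higher group, no overlap between the libraries of the groups, which for the mean over days was required within each day), up to 4 members per described list with the smallest p, and 18 genes named in advance for endoderm, pluripotency, glycolysis, lactylation and vitamin B6. Afp at days 5 and 7 was added after its values were seen.

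Fragment length was derived as annotated transcript length minus effective length, where effective length was the expected count divided by the product of FPKM and the library total, in the units of FPKM, and the median was taken over 577 genes with a single transcript, at least 100 counts and an FPKM of at least 3. The correction for GC content and length fitted, per library, a robust spline (5 degrees of freedom for each property) to the log2 deviation of genes with a mean CPM of at least 1 and entered it as an offset. The length was the effective length derived from the deposited values. The correction could be made for the 15815 genes with both properties, 83.7% of those tested. Of the 11 Hox genes tested only 5 had an effective length, so the corrected test of that list is void. On data simulated for the day 5 comparison without a trend, the uncorrected fit recovered 91% of genes changed by a log2 of 1 and 59% of those changed by 0.5, with 5 false calls among 18070 genes. With the trend of the vehicle day 5 libraries added, false calls were 8980 of 18104 genes uncorrected and 7 of 15815 corrected, which recovered 89% and 59%. The added trend had the form that the correction fits, so its removal was built in. The simulation does not show that the correction removes other effects of short fragments.

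Alternatives chosen in advance were DESeq2 1.42.0 and its size factors in edgeR, no filter, a stricter filter, only the libraries of the groups compared, a replicate block, a log2 fold change of at least 1, limma on log2(TPM + 1) and log2(TPM + 0.1), leaving out each library, an estimated correlation, fry, and other settings of the axis and terms. Chosen after seeing the data were the GC content and length correction alone and with the block, the mean of days 5 and 7, a fragment length covariate, vehicle day 7 against day 3, and another axis for day 7. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.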

Results

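The series measured RNA by sequencing in E14 mouse embryonic stem cells (ES cells, taken from the inner cell mass of the blastocyst and able to form every tissue of the embryo). The 21 libraries fell into 7 groups of 3. Untreated cells kept in standard culture formed the ES group, and cells carried through differentiation were collected at days 3, 5 and 7 with vehicle or with 20 µM pyridoxine, a form of vitamin B6 (VB6). How differentiation was started is not given in the sources used here. The question the series names is whether vitamin B6 moves these cells toward endoderm, the germ layer that forms gut, liver and pancreas, by way of glycolysis and histone lactylation. Total expected counts per library ran from 15882380 to 21629730 with a median of 17972485, and 25500 to 27758 genes had at least 1 count. Pairs of libraries from one group differed by a chi-square of 2.27 to 18.96 per gene, where counting error alone gives about 1. The labels do not say whether the 3 libraries of a group came from separate cultures, so the spread between them may be technical. Levels are given as CPM, counts scaled by edgeR to a common library size, with the SD over the 3 libraries, and fold changes as log2 values with their SE (n = 3 libraries per group). A count of 0 in a library is compatible with up to 3 counts, or 0.139 to 0.189 CPM across libraries, which covers counting error only.

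The libraries of 2 groups stood apart from the others in implied fragment length and in the shares of some classes of genes. Fragment length implied by the FPKM values was 227 ± 8.66 nt in vehicle day 5 and 266 ± 7.81 nt in VB6 day 7, against group means of 307 to 312 nt in the other 5 groups. The same 2 groups held fewer reads from ribosomal protein genes, at 3.84 ± 0.158% in vehicle day 5 and 3.65 ± 0.109% in VB6 day 7, where the other groups had 5.95 to 7.12%. Mitochondrially encoded genes took 4.33 ± 0.215% of reads in vehicle day 5 and 3.32 ± 0.271% in VB6 day 7, against 1.76 to 2.79% elsewhere. Mean GC content of the counted genes was lowest in vehicle day 5, at 47.5 ± 0.135%, and was 48.5 ± 0.174% in VB6 day 7. One of these groups is the vehicle arm at day 5 and the other the VB6 arm at day 7, so fragment length was confounded with VB6 at both days and in opposite directions, while at day 3 the fragment lengths of the arms overlapped. The libraries of the day 3 arms did not overlap in other properties: vehicle and VB6 had a mean GC content of 48.9 ± 0.152% and 48.7 ± 0.021%, mitochondrially encoded reads of 2.42 ± 0.126% and 2.79 ± 0.141% and ribosomal protein reads of 6.39 ± 0.334% and 7.12 ± 0.155%. Every comparison was therefore also fitted after a correction of each library for its own trend over GC content and gene length, an alternative chosen after seeing the data, and values from that fit are called corrected.

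**Figure D1:**
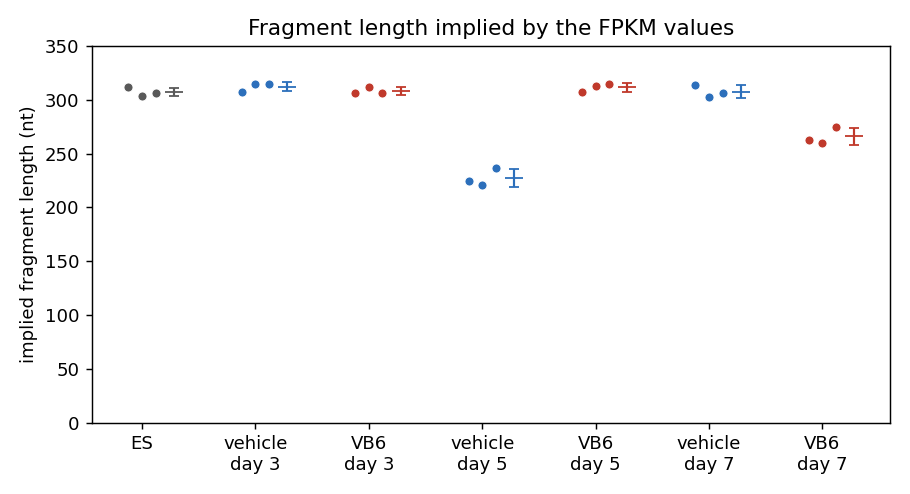
Fragment length in nt implied by the FPKM values (y axis) in each of the 21 libraries (points) by group (x axis), with the group mean and SD as a bar. The libraries of vehicle day 5 and VB6 day 7 lie below those of the other 5 groups.

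The levels of a few marker genes show the course of the culture. Pou5f1 (ENSMUSG00000024406, mm10 chromosome 17, 35506018 to 35510772), the core pluripotency factor Oct4, went from 1160 ± 68.5 CPM in ES cells to 884 ± 42.9, 207 ± 18.1 and 76.2 ± 9.33 CPM in vehicle at days 3, 5 and 7. Fgf5 (ENSMUSG00000029337, chromosome 5, 98254184 to 98277030), a marker of the postimplantation epiblast, had 0 counts in the ES libraries and stood at 92.3 ± 0.533, 137 ± 3.66 and 39.1 ± 4.23 CPM at those days. Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354), an endoderm transcription factor, was at 2.22 ± 0.439 CPM in ES cells and reached 40.9 ± 4.89 CPM in vehicle day 7. Afp (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907), the alpha-fetoprotein of visceral endoderm and fetal liver, rose from 0.919 ± 0.431 CPM in vehicle day 3 to 1080 ± 7.72 CPM in vehicle day 7. Apoa1 (ENSMUSG00000032083, chromosome 9, 46228580 to 46230466), an apolipoprotein of the same tissues, went from 0.975 ± 0.328 to 151 ± 14.7 CPM over those days. Ldha (ENSMUSG00000063229, chromosome 7, 46841475 to 46855627), which turns pyruvate into lactate, stayed between 1480 ± 33.8 CPM in VB6 day 7 and 2280 ± 56.6 CPM in vehicle day 3 in all 7 groups.

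**Figure D2:**
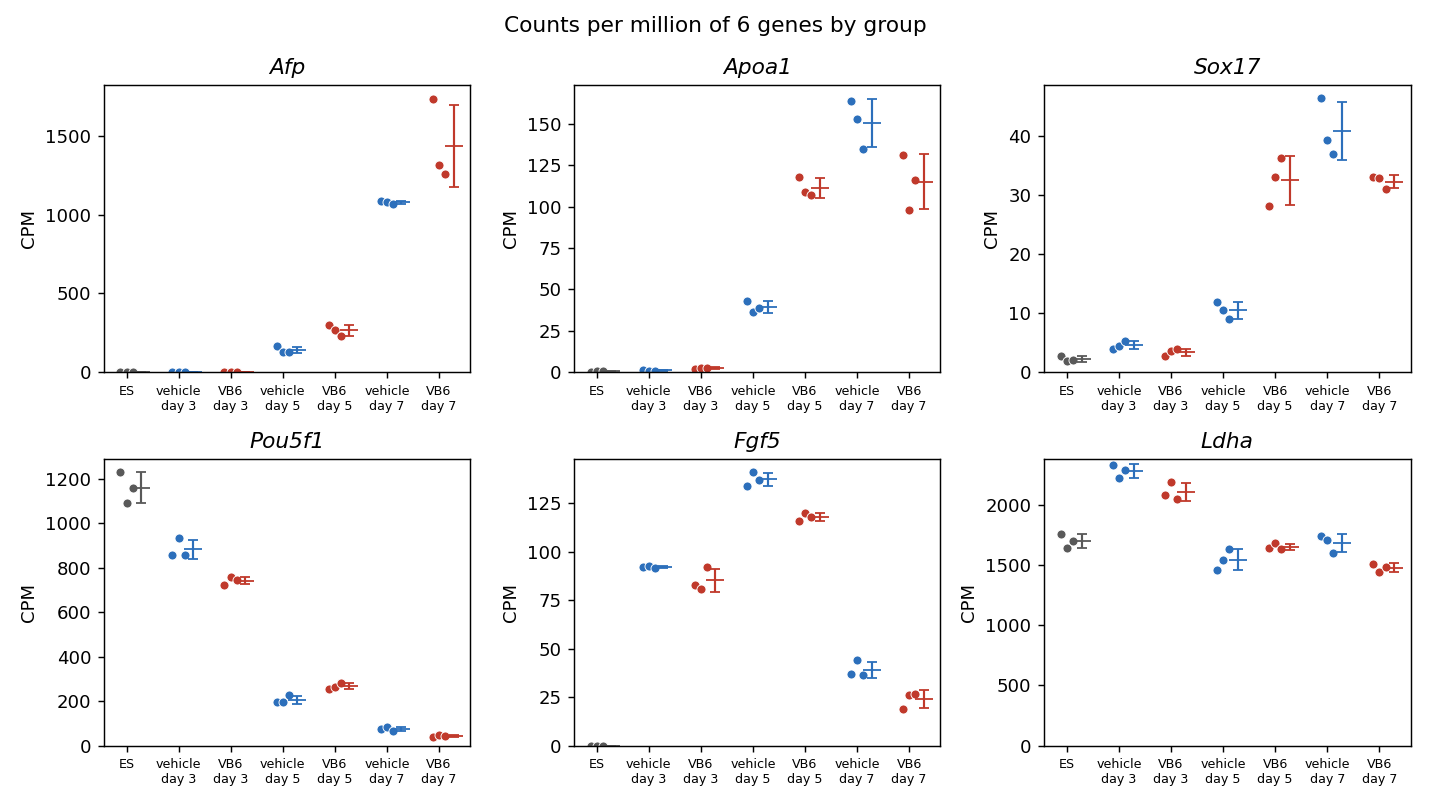
CPM (y axis, linear, one scale per gene) of Afp, Apoa1, Sox17, Pou5f1, Fgf5 and Ldha in the 21 libraries (points) by group (x axis), with the group mean and SD. Afp and Apoa1 were near 0 until day 3 and high at day 7, and Pou5f1 was lower at each later day.

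The first vehicle comparison, day 3 against ES, shows the change in cells that left standard culture without VB6. All 14 naive pluripotency genes tested fell (median log2 fold change −2.36). Among them were Tfcp2l1 (−3.81 ± 0.08) and Esrrb (−3.09 ± 0.08), transcription factors of the naive state, Tcl1 (−3.00 ± 0.10) and Zfp42 (−2.19 ± 0.08), the ES cell marker Rex1. Nanog fell by 1.24 ± 0.08 and Sox2 by 0.99 ± 0.10, and Pou5f1 fell by only 0.39 ± 0.08. Formative and primed epiblast genes moved the other way, with 10 of 11 higher and 1 lower. Otx2 rose by 4.51 ± 0.08, Pou3f1 by 4.44 ± 0.12 and the de novo DNA methyltransferase Dnmt3b by 3.72 ± 0.09. Visceral endoderm and hepatic genes followed, with 10 of 14 higher and 1 lower, led by Apob (9.43 ± 0.25), the main protein of secreted lipoproteins, Ttr (8.58 ± 0.43), a carrier of thyroid hormone, and Cubn (4.02 ± 0.12), a receptor of the visceral endoderm surface. Of 10 primitive streak and mesendoderm genes, 6 rose and 1 fell, or 7 and 1 adjusted over the list alone. Lhx1 was higher by 6.93 ± 0.53, Mixl1 by 3.46 ± 0.59 and Eomes by 2.60 ± 0.15. Primitive and parietal endoderm genes rose in 8 of 12 and fell in 1 (2 adjusted over the list alone), with Dab2 at 3.76 ± 0.08 and Sox7 at 2.64 ± 0.18. Among definitive endoderm genes, whose test gave an adjusted p of 0.121, Foxa2 rose by 3.51 ± 0.23, Sox17 by 1.04 ± 0.19 and Gata4 by 1.36 ± 0.10, and Krt19 fell by 1.2 ± 0.13.

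Signalling and metabolism moved as well in vehicle day 3. Nodal signalling genes rose in 8 of 9 and fell in 1, and the feedback inhibitors Lefty1 (3.29 ± 0.14) and Lefty2 (2.42 ± 0.11) were among them. Genes of pyruvate dehydrogenase and the citric acid cycle fell in 16 of 22 and rose in 1. Mpc1, a subunit of the mitochondrial pyruvate carrier and the member with the smallest p, fell by 2.10 ± 0.11. Oxidative phosphorylation genes fell in 21 of 30 (median −0.25), with Uqcrc1 at −0.89 ± 0.06, whereas the mitochondrially encoded genes rose in 10 of 13 (median 1.09), with mt-Cytb at 2.25 ± 0.08. Vitamin B6 handling genes fell in 7 of 9, or 8 adjusted over the list alone, among them the phosphatases Alpl (−0.79 ± 0.10) and Pdxp (−0.79 ± 0.11) and the kinase Pdxk (−0.28). Targets of p53 fell in 9 of 12, with the cell cycle inhibitor Cdkn1a at −1.87 ± 0.07. The glycolysis list was not called (10 higher, 7 lower of 23, adjusted p = 0.87), with Hk1 at −2.08 ± 0.09 and Pdk1 at 1.12. Other strong changes were in Irgm1 (8.68 ± 0.28), an interferon-induced GTPase, Inhbb (−6.86 ± 0.16), an activin subunit, and Socs3 (−5.83 ± 0.15), an inhibitor that cytokines acting through STAT3 induce. Psmb8, a subunit of the immunoproteasome, was at 15.8 ± 2.06 CPM in vehicle day 3 and had 0 counts in ES cells.

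In this comparison 12271 of 18901 genes were called at an adjusted p under 0.05 (edgeR quasi-likelihood test), 6261 higher and 6010 lower. The gene list test (camera, correlation preset) called 11 lists. Naive pluripotency had an adjusted p of 2.51e-08 and was the only list called with an estimated correlation, where its adjusted p = 0.0256. The others had adjusted p from 2.74e-07 (formative) to 0.0363 (vitamin B6 handling), and from 0.155 to 0.51 with an estimated correlation.

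From day 3 to day 5 in vehicle the visceral endoderm and hepatic program took over, with 13 of 14 genes higher and none lower (median log2 fold change 2.97). Afp rose by 7.22 ± 0.21, Apoa1 by 5.33 ± 0.18, Apob by 3.67 ± 0.11 and the fibrinogen chain gene Fgb by 5.52 ± 0.36. Primitive and parietal endoderm genes rose in 8 of 12 (median 0.54), with Dab2 at 1.80 ± 0.07, Pdgfra at 1.46 ± 0.11 and Sparc, a matrix glycoprotein, at 0.94 ± 0.07. Definitive endoderm genes were higher in 7 of 14 and lower in 1 (adjusted p = 0.0747), including Krt19 (2.23 ± 0.13), Sox17 (1.2 ± 0.15), Gata4 (1.14 ± 0.09) and Foxa2 (0.92 ± 0.14). Mixl1, a primitive streak factor, rose by 2.47 ± 0.30 from a low level. Pluripotency receded, with 10 of 13 general pluripotency genes lower and 2 higher (median −1.79), and 8 of 14 naive genes lower and 4 higher (median −1.26). Pou5f1 fell by 2.10 ± 0.08, Sox2 by 1.82 ± 0.11, the methylation cofactor Dnmt3l by 2.53 ± 0.07 and Nr0b1 by 3.36 ± 0.18. Formative genes fell in 7 of 11 and rose in 2 (median −0.82). Acta2, a smooth muscle actin, rose by 6.42 ± 0.31.

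Metabolic lists fell between these days. Oxidative phosphorylation genes fell in 27 of 30 and rose in 2 (median −0.78), with Ndufb8 at −1.33 ± 0.07. Serine and one-carbon genes fell in 13 of 18 and rose in 1, with Shmt2 at −1.46 ± 0.10 and Phgdh, the entry enzyme of serine synthesis, at −1.03 ± 0.06. Cholesterol synthesis genes fell in 13 of 16 and rose in 1, with Fdps at −1.30 ± 0.08. Pyridoxal phosphate enzymes, which use the active form of vitamin B6 as cofactor, fell in 20 of 34 (22 adjusted over the list alone) and rose in 9. Glycolysis genes fell in 17 of 23 and rose in 5 (median −0.43). The glycolytic enzymes Tpi1 (−0.85 ± 0.06) and Pkm (−0.88 ± 0.06) fell, while the lactate carrier Slc16a1 (1.82 ± 0.07) and the glucose transporter Slc2a3 (1.32) rose. Nodal signalling genes fell in 5 of 9 (median −0.42), or 5 lower and 1 higher adjusted over the list alone, with Lefty1 at −2.54.

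The vehicle day 5 libraries of this comparison had the short fragments, the low GC content and the low ribosomal protein share given above. The test called 12343 genes, 6037 higher and 6306 lower, and on the TPM scale, where the median gene shifted by 0.236, 71.3% of calls were higher against 48.9%. All 11 lists named as falling or rising in these paragraphs apart from definitive endoderm were called by camera, with adjusted p from 8.38e-08 (visceral endoderm) to 0.0488 (formative and Nodal), and none with an estimated correlation (adjusted p from 0.248 to 0.673). After correction the calls of formative (adjusted p = 0.0785), glycolysis (0.324), pyridoxal phosphate enzymes (0.104) and Nodal (0.146) ended, and definitive endoderm was called at 0.00752 (0.216 with an estimated correlation).

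Between days 5 and 7 in vehicle, genes of several differentiated tissues rose together. Visceral endoderm and hepatic genes rose in 13 of 14 and fell in 1 (median 2.36), with Rbp4 (3.42 ± 0.15), Afp (2.94 ± 0.12), Apom (2.90 ± 0.13) and Ttr (2.43 ± 0.10). Gut, pancreas and lung endoderm genes rose in 6 of 8, with the intestinal factor Cdx2 at 2.84 ± 0.24 and the pancreatic factor Nkx6-1 at 6.31 ± 0.59. Mesoderm genes rose in 9 of 10 (median 2.25), with Hand1 at 3.48 ± 0.20 and Kdr at 2.91 ± 0.32, and all 9 BMP targets rose, with Id3 at 2.63 ± 0.07. Fibroblast genes rose in 7 of 9 and fell in 1, with the collagens Col1a1 (5.03 ± 0.19) and Col1a2 (5.99 ± 0.19). Primitive and parietal endoderm genes rose in 9 of 12 and fell in 2, with the basement membrane collagen Col4a2 at 2.34 ± 0.11. Definitive endoderm genes rose in 10 of 14 and fell in 1. The neural genes Sox1 (4.27 ± 0.18) and Pax6 (2.68 ± 0.21) were higher too. Immediate early and heat shock genes rose in 11 of 12 and fell in 1, with Junb at 2.79 ± 0.12. On the falling side were 10 of 13 general pluripotency genes and 9 of 11 formative genes, each with 1 higher, including Pou5f1 (−1.44 ± 0.08), Otx2 (−1.53 ± 0.07) and L1td1 (−1.52 ± 0.08). Nanog fell by 1.58 ± 0.09 and Eomes by 1.17 ± 0.12. Oxidative phosphorylation genes rose in 24 of 30 and fell in 2 (3 adjusted over the list alone), and mitochondrially encoded genes fell in 9 of 13 and rose in 1.

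This comparison shares the short-fragment vehicle day 5 libraries. It called 12526 genes, 6652 higher and 5874 lower, or 37.9% higher on the TPM scale (median shift −0.134) against 53.1%. The 12 lists above were called with adjusted p from 0.000101 (visceral endoderm) to 0.0337 (definitive endoderm), and none with an estimated correlation (adjusted p from 0.217 to 0.564). After correction definitive endoderm was no longer called (7 higher and 2 lower of 12, adjusted p = 0.287), nor were the mitochondrially encoded genes (0.987), and the corrected values were 1.37 for Sox17 against 1.96 ± 0.12 and 1.07 for Foxa2 against 1.76 ± 0.12. Vehicle day 7 against day 3, which leaves those libraries out and was chosen after seeing the data, called 12747 genes and had Sox17 higher by 3.17 ± 0.14, Foxa2 by 2.68 ± 0.13, Afp by 10.17 ± 0.21 and Ttr by 4.39 ± 0.12, with Pkm lower (−0.76 ± 0.06), Hk2 lower (−0.67 ± 0.05) and Ldha lower (−0.44 ± 0.05).

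At day 3 the VB6 cells had less pluripotency and epiblast expression than vehicle and slightly more expression of visceral endoderm genes. Of 14 naive pluripotency genes 4 fell, or 9 adjusted over the list alone (median −0.29), led by Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), a naive state transcription factor, at −0.93 ± 0.15 (47.1 ± 9.11 CPM in vehicle, 24.7 ± 1.07 in VB6). Tcl1 fell by 0.63 ± 0.11, Nr0b1 by 0.58 and Zfp42 by 0.34. General pluripotency genes fell in 7 of 13, or 9 with 1 higher adjusted over the list alone (median −0.31). Dnmt3l fell by 0.45 ± 0.06, Dppa2 by 0.47 ± 0.10 and Sox2 by 0.44 ± 0.10. Pou5f1 was at −0.25 ± 0.08 without passing the test (adjusted p = 0.057, or 0.0118 corrected), and Nanog was at 0.16 (adjusted p = 0.296). Formative genes fell in 5 of 11 (6 adjusted over the list alone), with Lef1, a mediator of Wnt signals, at −0.92 ± 0.13, Pou3f1 at −0.68 ± 0.09 (−0.33 corrected) and Dnmt3a at −0.42 ± 0.06. Targets of FGF and ERK signalling fell in 4 of 10 (8 adjusted over the list alone), among them the ERK pathway inhibitor Spry4 (−0.54 ± 0.10) and Etv4 (−0.55 ± 0.12). Smad7, an inhibitor of TGF-beta signals, fell by 0.55 ± 0.11 and was the 1 called member of 9 BMP targets (4 adjusted over the list alone). With Lefty2 (−0.38) it made up the 2 called of 9 Nodal genes (4 adjusted over the list alone).

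Stress response genes were lower at day 3 as well. The amino acid response list of ATF4 targets fell in 7 of 14 (8 adjusted over the list alone), with Chac1 (−0.74 ± 0.16), Trib3 (−0.56 ± 0.13), the amino acid transporter Slc7a5 (−0.36 ± 0.07) and asparagine synthetase, Asns (−0.20 ± 0.05). Hypoxia response genes without glycolysis fell in 5 of 14 (7 adjusted over the list alone), with Adm at −0.83 ± 0.17 and Vegfa, the vascular growth factor, at −0.54 ± 0.10. Visceral endoderm and hepatic genes rose in 3 of 14 (5 adjusted over the list alone; median 0.27): Apoa1 by 1.29 ± 0.27 (2.36 ± 0.38 CPM against 0.975 ± 0.328), Ttr by 0.54 ± 0.14 and Apob by 0.35 ± 0.10, with Afp at 1.19 ± 0.38 (adjusted p = 0.0807). No definitive endoderm gene of 14 was called, with Sox17 at −0.43 (adjusted p = 0.174), Foxa2 at −0.24 (0.397) and Gata4 at 0.06 (0.751). Mitochondrially encoded genes rose in 1 of 13 (6 adjusted over the list alone, median 0.21), which was mt-Nd3 (0.69, or 0.42 with an adjusted p of 0.0734 corrected), and no single one of 30 oxidative phosphorylation genes was called (median 0.11). Among other called genes, Gabrp (1.41 ± 0.34), Fam110c (1.15) and Crabp2 (0.70), a carrier of retinoic acid, rose, and Gbx2 (−1.64 ± 0.33), Skor1 (−1.60) and Robo4 (−1.36 ± 0.24) fell. Alpl, which dephosphorylates pyridoxal phosphate outside the cell, fell by 0.59 ± 0.10.

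Of 18901 genes 805 were called at day 3, 281 higher and 524 lower, with 1137 by DESeq2 and 3750 at an unadjusted p under 0.05. On the TPM scale 20.6% of calls were higher against 34.9%. Without the library vehicle_day3 replicate 2 the count was 192, and it was 253, 294 and 398 without VB6 replicates 1, 2 and 3 and 366 without vehicle replicate 3. The 11 lists called, which are the 9 named above as falling or rising with both mitochondrial lists, had adjusted p from 2.1e-05 (ATF4 targets and FGF and ERK targets) to 0.0495 (Nodal), with visceral endoderm at 0.0054, and none was called with an estimated correlation (adjusted p from 0.133 to 0.541). Correction ended the calls of Nodal (0.0952), mitochondrially encoded (0.394) and oxidative phosphorylation genes, the last with its direction turned (0.882).

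At day 5 visceral endoderm and hepatic genes stood higher with VB6. Visceral endoderm and hepatic genes rose in 12 of 14 (median 1.26, or 0.776 corrected with 13 of 14 higher). Apoa1 was at 111 ± 6.07 CPM against 39.3 ± 3.35, a change of 1.5 ± 0.10 (0.77 ± 0.09 corrected). Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321) rose by 1.29 ± 0.10 (1.29 ± 0.09 corrected), Afp by 0.92 ± 0.12 (1.18 ± 0.11) and Apom by 1.68 ± 0.13 (1.03 ± 0.12). Primitive and parietal endoderm genes rose in 7 of 12 and fell in 1 (median 0.44), with Col4a2 at 1.61 ± 0.10 (0.91 corrected), Lama1 at 1.0 (0.73) and Sparc at 0.84 (0.50). Definitive endoderm genes were higher in 8 of 14 and lower in 1. Sox17 stood at 32.5 ± 4.15 CPM against 10.5 ± 1.49, a change of 1.63 ± 0.12 (1.03 ± 0.11 corrected), and Foxa2 rose by 1.06 ± 0.12 (0.38 ± 0.11). Krt19 rose by 1.16 (0.46 corrected), Gata4 by 0.65 ± 0.08 (0.15 with an adjusted p of 0.11) and Gata6 by 0.31 (−0.24 with an adjusted p of 0.0823), while Cxcr4, at 1.12 ± 0.369 and 1.57 ± 0.695 CPM, was not called. The primitive streak genes Eomes (−0.41, or −0.89 corrected) and Mixl1 (−0.69, or −0.64) fell. Sox2 rose by 1.12 ± 0.11 (0.99), Nanog fell by 0.56 ± 0.08 (−0.33), and Pou5f1 rose by 0.38 ± 0.08 but was lower after correction (−0.21 ± 0.07).

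Oxidative phosphorylation genes rose in 26 of 30 and fell in 3 (median 0.55, or 0.237 corrected), with Ndufb8 at 1.11 ± 0.07 (0.49 corrected), and mitochondrially encoded genes fell in 9 of 13 and rose in 2 (median −0.69), with mt-Co1 at −0.98. Glycolysis genes were higher in 11 of 23 (12 adjusted over the list alone) and lower in 3, with Tpi1 at 0.68 (0.21 corrected) and Pdk1 at −0.53. After correction 3 were higher and 11 lower. Some of the largest changes lay in genes with a near-identical copy, whose counts depend on how the authors' counting divided reads: Srp54b was at 19.2 ± 2.19 CPM against 0.309 ± 0.345, Ftl1-ps1 at 217 ± 21 against 8.82 ± 1.86, and Rnaset2b fell by 2.90. Outside such families, S100g, a calcium-binding protein of absorbing epithelia, rose by 2.97, and Prkcq fell by 2.38.

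The vehicle libraries of this day had the shorter fragments, with the lower GC content and ribosomal protein share. The test called 10716 genes, 5902 higher and 4814 lower, or 31.1% higher on the TPM scale (median shift −0.131) against 55.1%, and 2258 of them had a log2 change of at least 1. After correction 6136 of 15815 genes were called, 3973 of them in the same direction as before and 749 in the opposite one, with 217 higher and 348 lower by a log2 of at least 1. The lists called were visceral endoderm (adjusted p = 0.00103, or 7.01e-05 corrected), oxidative phosphorylation (2.16e-05, or 7.01e-05 corrected) and mitochondrially encoded genes (0.0274, or 0.766 corrected), each with an adjusted p of 0.824 with an estimated correlation. Definitive endoderm (0.249, or 0.766 corrected), primitive and parietal endoderm (0.0854, or 0.00171 corrected and 0.645 corrected with an estimated correlation) and glycolysis (0.18, or 0.105 corrected) were not called before correction.

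At day 7 VB6 cells had more expression of primitive and parietal endoderm genes and less of general pluripotency and immediate early genes. Primitive and parietal endoderm genes rose in 8 of 12, or 9 adjusted over the list alone (median 0.48), including the laminin chains Lamc1 (0.48 ± 0.07), Lama1 (0.54) and Lamb1 (0.40 ± 0.06), the last at 918 ± 79.2 CPM against 694 ± 29.6, and the endocytic adaptor Dab2 (0.43). Visceral endoderm genes were mixed, with 5 of 14 higher and 4 lower: Apob rose by 0.73 ± 0.10 (0.41 corrected), Cubn by 0.64 and Afp by 0.41 (0.27 corrected), while Apoa1 (−0.39) and Amn (−0.66) fell, both near 0 after correction (0.04 and 0.01). Among definitive endoderm genes 2 of 14 fell, Trh and Sox17 (−0.34 ± 0.11, or −0.04 corrected with an adjusted p of 0.784). Postn, a matrix protein of fibroblasts, rose by 1.55 ± 0.18, and Cp, the copper carrier ceruloplasmin made by the liver, by 1.63. General pluripotency genes fell in 8 of 13 (median −0.26), with Pou5f1 at −0.80 ± 0.09 (−0.48 corrected) and Sox2 at −0.63 ± 0.10. Formative genes fell in 5 of 11 (6 adjusted over the list alone) and rose in 1, with Pou3f1 at −1.02 and Fgf5 at −0.69 (24.1 ± 4.4 against 39.1 ± 4.23 CPM). Nodal signalling genes fell in 5 of 9, with Lefty1 at −1.81 ± 0.18 and Nodal at −0.93, and BMP targets in 5 of 9, with Id3 at −1.07 and Id1 at −0.89. Of 13 neural genes 5 fell, among them Sox3 (−1.26), Nes (−0.92) and Sox1 (−0.65), and 1 rose, and that list was not called (adjusted p = 0.308).

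Immediate early and heat shock genes fell in 10 of 12 at day 7 (median −0.83), among them Junb (−1.75 ± 0.12, or −1.2 corrected), Ier2 (−1.53) and Fos (−0.98). ATF4 targets fell in 9 of 14 and rose in 3. Oxidative phosphorylation genes fell in 26 of 30 (median −0.48), with 1 higher adjusted over the list alone, and Ndufb8 was at −0.78 (−0.26 corrected). Glycolysis genes fell in 12 of 23 (13 adjusted over the list alone) and rose in 3 (median −0.19). Pkm fell by 0.51 ± 0.06 (−0.36 ± 0.05 corrected), Tpi1 by 0.53 (−0.30) and Pfkl by 0.49. Ldha fell by 0.19 (−0.01 corrected, adjusted p = 0.854) and Slc2a1 by 0.19 (−0.08 corrected, adjusted p = 0.2).

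The VB6 libraries of day 7 were the ones with shorter fragments. The test called 6899 genes, 3524 higher and 3375 lower, or 82.9% higher on the TPM scale (median shift 0.194) against 51.1%, and 4506 after correction, 2961 of them in the same direction and 87 in the opposite one. Called lists were oxidative phosphorylation (adjusted p = 4.32e-11), immediate early (0.000373), primitive and parietal endoderm (0.00117), general pluripotency (0.00629), glycolysis (0.0122, or 0.121 corrected), Nodal (0.0168), BMP (0.0296), formative and ATF4 targets (each 0.0317, ATF4 0.379 corrected). None was called with an estimated correlation (adjusted p from 0.514 to 0.88).

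Averaged over the 3 days, the 9 VB6 libraries had more expression of visceral endoderm and hepatic genes than the 9 vehicle libraries. Primitive and parietal endoderm genes were higher too, and formative epiblast genes were lower. Which cells expressed these genes was not tested. Visceral endoderm and hepatic genes rose in 10 of 14, or all 14 adjusted over the list alone (median 0.53). The highest of these was Afp at 0.84 ± 0.14, followed by Apoa1 (0.80 ± 0.10), Ttr (0.54 ± 0.07) and Apoa4 (0.53 ± 0.09). The rise of this list was largest at day 5, where the vehicle libraries had the short fragments. By day 7 its members went both ways, with Afp higher and Apoa1 lower before correction. Primitive and parietal endoderm genes rose in 9 of 12 (median 0.28), with Lama1 (0.40), Lamb1 (ENSMUSG00000002900, chromosome 12, 31265234 to 31329644; 0.33 ± 0.04), Sparc (0.29) and Lamc1 (0.28). Plat (ENSMUSG00000031538, chromosome 8, 22757727 to 22782844), the tissue plasminogen activator, rose by 0.64 ± 0.08 and the fibrinogen chain gene Fgg by 0.59. Of 14 definitive endoderm genes 3 rose (4 adjusted over the list alone) and 1 fell: Gata4 by 0.30 ± 0.05, Sox17 by 0.29 ± 0.08 (0.19 with an adjusted p of 0.0857 corrected), Krt19 by 0.25 (0.15 with an adjusted p of 0.1 corrected) and, downward, Trh. The rise of Sox17 came from day 5, where the vehicle libraries had the short fragments. Its values at days 3 and 7 were negative. Foxa2 was at 0.22 (adjusted p = 0.0534). On the other side 8 of 11 formative genes fell (median −0.22), including Lef1 (−0.42), Fgf5 (−0.34 ± 0.05), Otx2 (−0.23) and Zic5 (−0.22). General pluripotency genes fell in 6 of 13 (7 adjusted over the list alone), with Dppa2 (−0.33) and Pou5f1 (−0.22 ± 0.05). Nodal genes fell in 5 of 9, with Lefty1 (−0.37), Lefty2 (−0.33), Skil (−0.31) and Nodal itself (−0.25). FGF and ERK targets fell in 5 of 10, with Egr1 (−0.62 ± 0.10) and Dusp6 (−0.27 ± 0.04). Bcl11a, a zinc finger repressor, fell by 0.85 ± 0.14, and Mcl1, a survival factor, fell by 0.27 ± 0.03. Genes of the two-cell-like state fell in 3 of 7 (4 adjusted over the list alone), among them Zscan4c (−0.47) and Zscan4f (−0.43). Fibroblast genes rose in 2 of 9, Col1a2 (0.56) and Col1a1 (0.51), or in 4 with 1 lower adjusted over the list alone. Hypoxia response genes fell in 5 of 14, or 7 with 1 higher adjusted over the list alone, with Egln3 at −0.25 and Bnip3 at −0.21, and cholesterol synthesis genes in 3 of 16 (5 adjusted over the list alone), with Idi1 at −0.26.

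The mean over days called 2218 genes, 1243 higher and 975 lower, or 39.4% higher on the TPM scale against 56%, and 2157 after correction, 1373 of which were called in both fits and none in opposite directions. Of 100 splits of the libraries within days 6, the real one included, called as many genes, so chance was not excluded for this count. It called the 10 lists just named other than definitive endoderm: visceral endoderm (adjusted p = 1.6e-10), primitive and parietal endoderm (1.1e-07), formative (1.75e-07), Nodal and FGF and ERK targets (each 0.00201), general pluripotency (0.00575), two-cell-like and fibroblast (each 0.0151), hypoxia and cholesterol (each 0.0492). With an estimated correlation none was called, visceral endoderm coming closest (adjusted p = 0.0788) and the others from 0.246 to 0.606. Day 3 libraries had like fragment lengths in both arms, and the opposite imbalances of days 5 and 7 partly offset each other in this mean. A gene called in the mean need not have like effects at each day. A model with a single VB6 effect beside day called 23 of 18318 genes.

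The remaining 27 lists were not called in the mean over days. Tissue lists had these counts and adjusted p: naive pluripotency 1 higher and 1 lower of 14 (0.922), primitive streak and mesendoderm 1 lower of 10 (0.133), definitive endoderm as given (0.278), gut, pancreas and lung 0 of 8 (0.159; 2 higher adjusted over the list alone), mesoderm 0 of 10 (0.373), cardiac muscle 1 higher of 10 (0.133; 3 adjusted over the list alone), blood and endothelium 0 of 9 (0.492), neural 1 lower of 13 (0.352; 2 adjusted over the list alone), surface ectoderm and neural crest 0 of 7 (0.837), trophoblast 2 higher of 7 (0.122; 3 adjusted over the list alone) and germ line 2 higher of 10 (0.786). Metabolic lists gave glycolysis and lactate 2 lower of 23 (0.352), pyruvate dehydrogenase and citric acid cycle 1 higher of 22 (0.92; 0 adjusted over the list alone), oxidative phosphorylation 2 higher of 30 (0.14), lactylation and acetylation enzymes 1 higher and 2 lower of 19 (0.425), vitamin B6 handling 1 higher of 9 (0.971), pyridoxal phosphate enzymes 1 higher and 2 lower of 34 (0.311), serine and one-carbon metabolism 3 higher and 1 lower of 18 (0.737; 4 and 2 adjusted over the list alone), ATF4 targets 0 of 14 (0.14) and mitochondrially encoded genes 2 lower of 13 (0.218; 1 higher and 2 lower adjusted over the list alone). The rest were Wnt targets 1 lower of 11 (0.679), BMP targets 1 lower of 9 (0.737), Hox genes 0 of 11 (0.218), proliferation 2 higher of 16 (0.92; 4 higher and 3 lower adjusted over the list alone), p53 targets 1 higher and 3 lower of 12 (0.218), immediate early and heat shock genes 3 lower of 12 (0.0729; 4 adjusted over the list alone) and interferon response 0 of 11 (0.492). Median, mean and test differed in sign for definitive endoderm, naive pluripotency, surface ectoderm, germ line, pyruvate dehydrogenase, vitamin B6 handling, Wnt and BMP. Correction brought calls for glycolysis (1 higher and 10 lower, adjusted p = 0.000128, or 0.348 with an estimated correlation), ATF4 targets (0.00156), immediate early (0.000944), primitive streak (0.0337), lactylation enzymes (0.0337) and mitochondrially encoded genes (0.0229). With an estimated correlation the adjusted p of these was 0.282 for ATF4 targets, 0.218 for immediate early, 0.348 for primitive streak and for lactylation enzymes and 0.346 for mitochondrially encoded genes.

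The VB6 effect itself differed between days for 11347 genes (7243 corrected). From day 5 to day 7 the effect on Sox17 changed by −1.97 ± 0.17 (−1.07 corrected), on Apoa1 by −1.89 (−0.73), on Ttr by −1.49 (−1.43) and on Sox2 by −1.75 ± 0.15 (−1.60). That on Junb changed by −3.36 (−1.79) and on Id3 by −2.45. The effect on visceral endoderm genes was lower at day 7 than at day 5 for 12 of 14 and higher for 2 (adjusted p = 0.0402), on oxidative phosphorylation genes lower for 26 of 30 and higher for 2 (1.35e-07) and on immediate early genes lower for 8 of 12 and higher for 1 (0.0396), each with an adjusted p of 0.912 with an estimated correlation. Of 5547 genes called at both days 5330 (96.1%) had opposite signs, and 2351 of 2684 (87.6%) after correction. Across genes the day 5 and day 7 effects correlated at r = −0.632 (rho −0.635) and at r = −0.549 (rho −0.348) corrected, over 15815 genes, which are not independent replicates. Day 3 effects had a corrected r of −0.0397 with day 5 and 0.0146 with day 7 across the same genes.

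**Figure D3:**
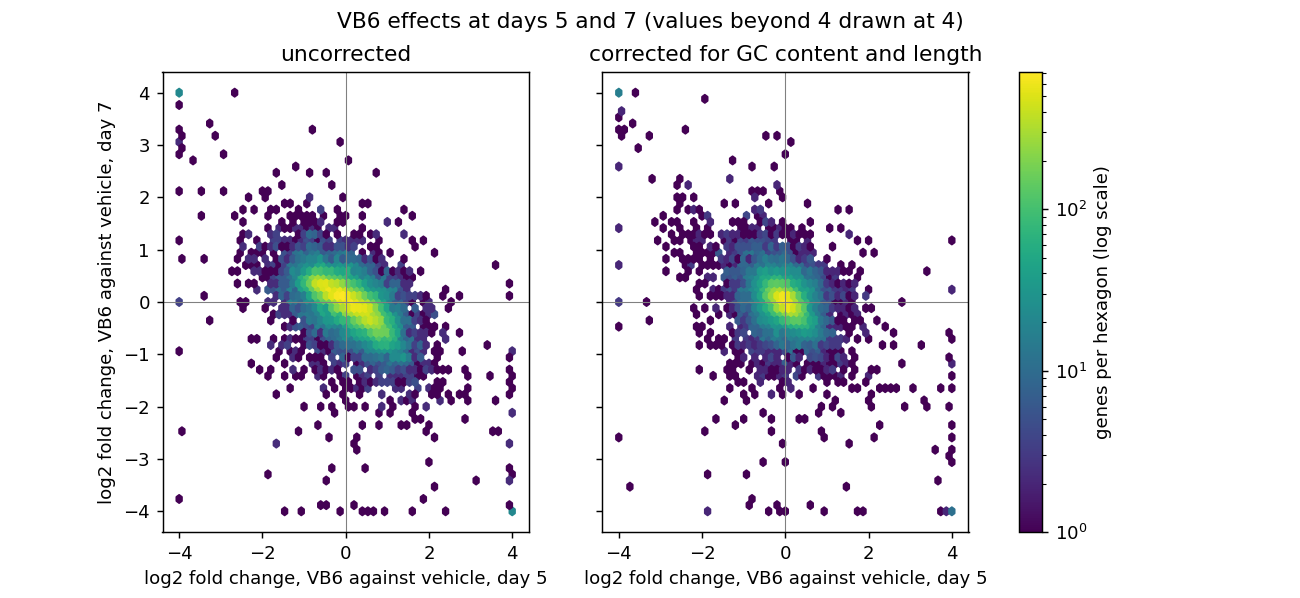
Log2 fold changes of VB6 against vehicle at day 5 (x axis) and day 7 (y axis), each hexagon coloured by its number of genes on a log scale, before (left) and after (right) the GC content and length correction. The slope from upper left to lower right weakened after correction, from r = −0.632 to −0.549 and from rho = −0.635 to −0.348 across genes.

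Position along the vehicle course asks how far each library lay from ES (0) toward a vehicle group of another day (1). The end was vehicle day 7 for days 3 and 5, and vehicle day 5, an earlier group, for day 7. Vehicle and VB6 stood at 0.438 ± 0.00351 and 0.467 ± 0.00751 at day 3, at 0.739 ± 0.00666 and 0.791 ± 0.0095 at day 5, and at 0.814 ± 0.0155 and 0.923 ± 0.0202 at day 7. Every VB6 library had a higher position than every vehicle library of its day. At day 7 a higher position means nearer to vehicle day 5, so it does not show cells farther along the course. The mean over days includes that day. The differences were 0.0295, 0.0523 and 0.109, each with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Their mean, 0.0635, had an exact permutation p of 0.00025, the smallest the 8000 permutations within days give, and with the correction it was 0.0514 with the same p. The end for day 7 was the group with short fragments. With vehicle day 3 as the end instead, an alternative chosen after seeing the data, the day 7 difference turned to −0.0212 and the mean fell to 0.0202 (exact permutation p = 0.0445).

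**Figure D4:**
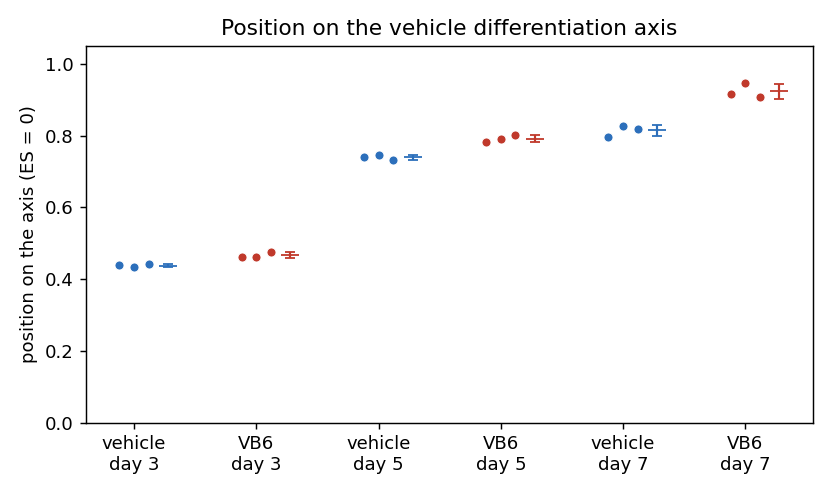
Position on the vehicle differentiation axis (y axis, ES at 0, no unit) of the 18 vehicle and VB6 libraries (points) by group (x axis), with the group mean and SD. At each day the VB6 libraries lie above the vehicle libraries.

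Glycolysis and lactylation genes, which the series' question names, showed small differences. Neither list was among those called for a VB6 effect that differed between days 5 and 7. At day 3 the glycolytic enzymes Pfkp (−0.27), Hk2 (−0.19 ± 0.05, or −0.13 corrected with an adjusted p of 0.106) and Pfkfb3 (−0.28, or −0.22 with an adjusted p of 0.089) fell, 3 of 23 list members, and the list was not called (adjusted p = 0.0983). Pkm, Ldha and Slc2a1 were not called at that day. At day 5 the glucose transporter Slc2a1 rose by 0.45 ± 0.06 (0.06 corrected, adjusted p = 0.338) and Pkm by 0.43 ± 0.06 (−0.01, 0.843), while Ldha was at 0.10 uncorrected and fell by 0.24 ± 0.04 after correction. After correction more members of the glycolysis list were lower than higher at day 5. As given above, the list was called lower at day 7 before correction, but not after it or with an estimated correlation. Pkm was lower at that day in both fits. In the mean over days Pdk1 (−0.15 ± 0.03) and Pfkp (−0.12 ± 0.04) fell. The list was called lower in that mean only after correction, and no longer with an estimated correlation too. Ldha (−0.07), Pkm (−0.06) and Hk2 (−0.07) were not called and after correction were called at −0.12, −0.14 and −0.12. Ep300, an acetyltransferase also reported to add lactyl groups, fell by 0.26 at day 5 (−0.18 corrected), rose by 0.21 at day 7 (0.06, adjusted p = 0.325) and was not called in the mean. Among lactylation and acetylation enzymes Sirt1 (−0.28 ± 0.04) and Kat2b (−0.24 ± 0.05) fell and Sirt2 rose (0.25 ± 0.05) in the mean over days.

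The vitamin B6 handling list was not called at day 3 (1 lower of 9, adjusted p = 0.566), day 5 (3 higher and 3 lower, 0.839) or day 7 (4 higher, 0.456). Alpl fell at day 3, as given above. Pdxk (ENSMUSG00000032788, chromosome 10, 78436744 to 78464975), which phosphorylates pyridoxine, was at 38.9 ± 2.18 and 37.0 ± 1.6 CPM in vehicle and VB6 at day 3, at 22.7 ± 2.03 and 26.9 ± 1.27 at day 5 and at 20.7 ± 1.7 and 19.4 ± 1.55 at day 7. Its day 5 rise of 0.25 ± 0.08 was −0.05 after correction (adjusted p = 0.673). Plpbp, a pyridoxal phosphate binding protein, rose by 0.14 ± 0.04 in the mean over days. Among pyridoxal phosphate enzymes the glycogen phosphorylase Pygb rose by 0.24 ± 0.04 and Cth fell by 0.19 in that mean.

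Annotation terms were searched without fixed lists (one-sided Fisher exact tests, 3367 terms). These tests, here and below, treat genes as independent, so their p values do not measure the spread between libraries. In the mean over days higher genes were enriched in lysosome (41 of 121 genes, 8.63 expected, adjusted p = 2.18e-14), collagen-containing extracellular matrix (47 of 201, 14.3 expected, 2.62e-10), stress fibre (25 of 69, 4.92 expected, 2.79e-09) and endocytosis (47 of 234, 16.7 expected, 4.83e-08). Lower genes were enriched in the cellular response to leukemia inhibitory factor, the cytokine that maintains ES cells (32 of 105, 5.62 expected, 8.91e-13). That term was also enriched among lower genes at day 3 (13 of 105, 3.08 expected, 0.0142), beside basement membrane (11 of 84, 2.46 expected, 0.0224), and higher genes of day 3 held glutathione transferase activity (8 of 26, 0.414 expected, 1.53e-05). At day 5 the ribosome (113 of 130, 43.6 expected, 3.85e-33) led the higher genes and the cell cycle (74 of 153, 39.4 expected, 2.18e-06) was among the lower. At day 7 the ribosome was among the lower genes (110 of 130, 24.7 expected, 6.11e-56), which goes with the ribosomal protein shares of the short-fragment libraries given above. In vehicle, day 3 against ES raised ribosome biogenesis (50 of 73, 25.1 expected, 4.5e-06), day 5 against day 3 raised lysosome (71 of 121, 39.4 expected, 9.18e-06), and day 7 against day 5 lowered the response to leukemia inhibitory factor (66 of 105, 32.2 expected, 7.95e-09). No term passed at day 3 or in the mean over days when only genes with a log2 change of at least 1 were used, where 15 and 5 terms at day 3 and 89 and 21 in the mean (higher and lower genes) had passed among all called genes.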

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

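The tests chosen after the result was seen were the corrected correlation of the day 5 and day 7 effects, the separate tests of definitive and visceral endoderm, the sums over gene copies and the splits that exchanged the labels of whole days.

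The VB6 effect differed between days for 11347 genes, and between day 7 and day 5 for 10910 genes. Of the lists, visceral endoderm and hepatic (adjusted p = 0.0402), oxidative phosphorylation (1.35e-07) and immediate early and heat shock genes (0.0396) differed between day 7 and day 5, each with an adjusted p of 0.912 with an estimated correlation. Among endoderm genes the day 7 effect minus the day 5 effect was −1.97 for Sox17 (−1.07 corrected), −1.23 for Foxa2 (−0.24) and −0.46 for Gata4 (turned to 0.21) on the log2 scale, and it was 1.71 for T (2.32 corrected), which marks mesoderm. Among pluripotency genes it was −1.18 for Pou5f1 (−0.27 corrected), 0.54 for Nanog (0.15) and −1.75 for Sox2 (−1.60). Among glycolysis genes it was −0.64 for Slc2a1 (−0.14 corrected), −0.24 for Hk2 (turned to 0.06), −0.95 for Pkm (−0.35) and −0.29 for Ldha (turned to 0.23, adjusted p = 0.00179 by edgeR). It was 0.48 for Ep300 (0.23 corrected) and −0.34 for Pdxk (−0.02). The FPKM table, which the uncorrected comparisons did not use, gave a mean fragment length of 227.2 nt in vehicle day 5 and 265.9 nt in VB6 day 7, below the ES libraries.

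The first pattern weighed is that VB6 effects at days 5 and 7 mirrored each other. Removing the fitted GC content and length trend left r = −0.549 across 15815 genes (−0.563 to −0.508 without each library in turn), against −0.632 before. It left rho = −0.348 (−0.371 to −0.316) against −0.635. The trend as fitted is thus not the whole cause, though the ranks lost more of their correlation with it. Effects of GC content or length that the fit does not capture stay possible. A shift in the timing of differentiation stays open. Across genes the corrected day 5 effect correlated at 0.205 with vehicle day 7 minus day 3, and the corrected day 7 effect at 0.426 with vehicle day 5 minus day 3. By the rule written beforehand, equal signs count against such a shift. That rule was set aside, because both effects in the day 7 value hold a short-fragment group. Fragment length is a candidate explanation. On uncorrected values and within groups, libraries with shorter fragments lay farther along the mirrored direction (r = 0.87, one-sided permutation p = 2e-05). By ranks rho was 0.89 (one-sided permutation p = 1e-05, the smallest 100000 permutations give). Without the 2 libraries farthest in fragment length r was 0.868. These values still hold the GC content and length trend, so they do not separate it from other effects of short fragments. RNA degradation, library preparation, a VB6 effect that turns between days or labels exchanged at day 5 or 7 may lie behind the pattern, and these cannot be told apart. Exchanging labels raised the calls of the mean over days (below) but also put the short-fragment groups on one side. Mirrored effects give that rise whatever their cause, so it is no reason to prefer exchanged labels.

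The second pattern is that visceral endoderm and hepatic genes, and some definitive endoderm genes, were higher with VB6 at day 5. The definitive endoderm list was not called, before or after correction. Over both endoderm lists the corrected median was 0.4 of the uncorrected one, which leaves open how much the GC content and length trend accounts for. For definitive endoderm that share was 0.0719 (0.376 to 0.0271, at percentile 60.8 of matched random lists after correction), but after correction Sox17 (1.03 ± 0.11) and Foxa2 (0.38 ± 0.11) were still called higher and Trh (−0.94 ± 0.13) lower, so a median over members that went both ways decides nothing. For visceral endoderm it was 0.616 (1.26 to 0.776, at percentile 100), so a part remained and its source cannot be told apart from other effects of short fragments. More cells of every differentiated type would need differences within 0.3 of mesoderm, neural and surface ectoderm genes, and the corrected visceral endoderm median exceeded these by 0.494, 0.671 and 0.694, which runs against it for that list without passing 0.5 for each, the bound set to exclude it, while definitive endoderm lay within 0.3 of all 3 (−0.255 for mesoderm), so it stays open.

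The third pattern is that some of the strongest changes at days 5 and 7 were in genes with near-identical copies. Reads divided differently between copies could produce them, and the sum over copies moved by less than 0.5 log2 at both days in 3 of 6 families examined: Srp54 (−0.348 and 0.239), Rnaset2 (0.261 and −0.0549) and Commd1 (−0.0918 and −0.148). It moved more in Ftl1 (3.47 and −4.19), Erh (0.308 and −0.62) and Pam16 (0.825 and −0.577), so for the set as a whole division of reads and real change cannot be told apart. Other genes among the largest changes, such as Exosc6 (4.99 and −4.92) and H2ac7 (3.15 and −3.41), were not examined in this way.

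Other splits of the libraries were counted for each comparison. For groups of 3 against 3 there are only 10 splits, too few for a share under 0.05, and in each such comparison 1 split, the real one, gave as many genes. The real split called 2104 genes at day 3 (highest other 2), and at day 5 10588, at day 7 6229, in vehicle day 3 against ES 11167, in day 5 against day 3 12072 and in day 7 against day 5 12008, each with a highest other of 0. For the mean over days 6 of 100 splits gave as many genes as the real one (2667, highest other of the 100 at 7361), so chance was not excluded for that count. For the difference between days 1 of 100 splits, the real one, gave as many (11540, highest other of the 100 at 7227). That count thus followed the groups more than random divisions of these libraries did. The libraries of a group may not be separate cultures, and whole groups differed in fragment length. The splits therefore cannot tell VB6 from other differences between groups. Beyond these 100, 2 splits that follow fragment length were fitted: with day 7 labels exchanged 9632 genes were called for the mean over days and 9810 for the difference between days, and with those of days 7 and 3 exchanged, the mirror of exchanging day 5 alone, 10198 and 9151. Those counts for the mean are several times the real one. Mirrored effects at days 5 and 7 give such a rise whatever their cause, so it does not decide between causes. The counts for the difference between days stayed below the real one.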

How the results depend on the processing

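The alternatives chosen after seeing the data were the GC content and length correction alone and with the block, the mean of days 5 and 7, the fragment length covariate, vehicle day 7 against day 3 and the other axis for day 7. Of 320 alternatives for 27 counts and positions, 262 stayed within 1.5 times the reported count or within its spread, 57 moved further and 1 reversed. Of 4036 for 303 single gene values, 3816 stayed on their side of the threshold, 173 lost the call, 30 gained one and 17 reversed. Of 1480 for 296 list tests, the numbers were 1251, 105, 118 and 6. A gene or list counted as reversed only where its sign turned and at least 1 of the fits called it. Uncalled values that changed sign are therefore among those that stayed. Unless said otherwise, the cause was not tested. Depth limits statements on genes near 0 counts, which 3 counts per library bound.

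With the correction, which tests fewer genes, the calls were 1261 at day 3, 6136 at day 5, 4506 at day 7 and 7243 for the difference between days, and the axis differences were 0.0606 at day 5 and 0.0604 at day 7. With vehicle day 3 as the end of the axis the day 7 difference reversed to −0.0212. Day 3 gave 1393 calls with no filter, 2104 with only the libraries of the groups compared, and 277 and 200 with limma on log2(TPM + 1) and log2(TPM + 0.1). A log2 fold change of at least 1 left fewer genes by construction: 47, 2258 and 790 at days 3, 5 and 7, 60 for the mean over days, and 5111, 4635 and 4732 for the vehicle comparisons in order of time. The mean over days gave 4491 as the mean of days 5 and 7 and 1309 with limma on log2(TPM + 0.1). A model with a single VB6 effect beside day called 23 genes, and 1036 with a fragment length covariate added, so that count differs from the reported one in the form of the model too. The fragment length term in that fit called 11070 genes.

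Without each library in turn, calls ranged from 192 to 850 at day 3, 9793 to 10234 at day 5, 5407 to 6636 at day 7, 1565 to 2482 for the mean over days, 10791 to 11408 for the difference between days, and 11612 to 11865, 11547 to 11820 and 11711 to 12051 for the vehicle comparisons. The axis differences ranged from 0.0249 to 0.0321, 0.044 to 0.0615 and 0.0972 to 0.116 at days 3, 5 and 7, and from 0.0586 to 0.0664 for their mean.

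Of the lists called, an estimated correlation left 0 in every comparison except vehicle day 3 against ES, which kept 1. The preset correlation had called 11, 3, 9 and 10 for VB6 at days 3, 5, 7 and in the mean, 11, 11 and 12 for vehicle, and 3 for day 7 minus day 5. Fry, which asks another question, called 6, 22 and 15 at days 3, 5 and 7, 28, 30 and 26 in vehicle, and 24 for day 7 minus day 5. Correction called 8 at day 5, visceral, primitive and parietal endoderm and oxidative phosphorylation higher and formative, primitive streak, hypoxia, cholesterol and Nodal lower, and 16 in the mean. With an estimated correlation too it called none of the 8 (adjusted p from 0.23 to 0.799) and 4 of the 16 (visceral endoderm, formative, Nodal and FGF and ERK targets, each 0.0452). Vehicle day 5 against day 3 called 6 with only its own libraries. Lists that reversed with correction were oxidative phosphorylation at day 3 (adjusted p = 0.882), Nodal at day 5 (0.0427, or 0.645 with an estimated correlation too), mitochondrially encoded genes in the mean (0.0229, or 0.346) and vehicle day 7 against day 5 (0.987), and glycolysis in the latter (0.00357, or 0.54). Targets of p53 reversed with fry for day 7 minus day 5 (0.011). With correction 37 terms passed at day 3, and the number of annotation terms, Vehicle day 5 against day 3, was 367. With a log2 fold change of at least 1 they were 0, 68, 33 and 0 for VB6 at days 3, 5, 7 and the mean and 66 for vehicle day 5 against day 3.

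Single genes reversed with the correction, as log2 values. At day 5 these were Pou5f1 (−0.21), Gata6 (−0.24), Hk2 (−0.14), Ldha (−0.24), Pkm (−0.0134), Pdxk (−0.0465), Sox3 (−0.295) and Cth (0.11). At day 7 they were Apoa1 (0.0412), Amn (0.00821), Pdk1 (−0.027) and Sirt1 (−0.29), in vehicle day 7 against day 5 Ldha (−0.21) and Pkm (−0.34), and for day 7 minus day 5 Gata4 (0.21), Hk2 (0.0579) and Ldha (0.23).

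Replicate numbers did not pair the libraries: same-number correlations of deviations ran from −0.236 to 0.147, and not every library correlated best with its own number. With the replicate number as a block the calls were 771, 10634 and 6816 at days 3, 5 and 7, 2205 for the mean, 11252 for the difference between days and 12211, 12283 and 12429 in vehicle, and 6 lists for vehicle day 5 against day 3. With block and correction they were 1240, 6093, 4490, 2153, 7187, 11502, 10693 and 10039.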

Other observations

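The tests reported here on corrected values were chosen after seeing the data.

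At day 5 some genes of further tissues were higher with VB6, in lists that were not called. Over all tested genes 5902 of 18901 were called higher at that day. Among 10 cardiac muscle genes 5 rose and none fell (adjusted p = 0.245), with the myosin chains Myh7 at 1.84 ± 0.25 (1.43 ± 0.24 corrected) and Myh6 at 1.01 ± 0.16 (0.49 ± 0.13 corrected). Trophoblast genes rose in 5 of 7 (adjusted p = 0.249), with Krt7 at 1.08 ± 0.17 (0.69 corrected) and Gata3 at 0.97 ± 0.29 (0.69 corrected). Neural genes rose in 5 of 13 and fell in 1 (adjusted p = 0.723), with Sox1 at 1.64 ± 0.21 (1.17 corrected), while Sox3 was at 0.79 and turned to −0.29 after correction. Gut, pancreas and lung genes rose in 3 of 8 and fell in 1 (adjusted p = 0.392), with Cdx2 at 1.5 ± 0.26 (0.89 corrected). None of these lists was called. The vehicle libraries of that day had the shorter fragments.

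In the mean over days the terms of retroelement proteins were enriched among lower genes: aspartic-type endopeptidase activity (15 of 42 genes, 2.25 expected, adjusted p = 1.96e-06), DNA integration (18 of 69, 3.69 expected, 8.02e-06) and RNA-mediated transposition (15 of 52, 2.78 expected, 2.54e-05). Such genes have many similar copies, and their counts are uncertain for that reason. DNA methylation was also enriched among lower genes (7 of 17, 0.91 expected, 0.00335), and tight junction (33 of 146, 10.4 expected, 9.17e-07) and actin filament binding (37 of 175, 12.5 expected, 9.17e-07) among higher genes. After correction glycolytic process was enriched among lower genes (17 of 45, 3.24 expected, 3.43e-06).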
